A study of Mus musculus with 12 samples.

How the data were processed

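The series holds RNA-seq of mouse skin in 4 groups of 3 libraries, whole skin and epidermis of wild type mice and of mice with a conditional Adam17 knockout, all at 10 weeks of age, made with a stranded poly(A) kit per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited tables give 1 expected count per gene and library, estimated by RSEM after alignment with STAR 2.5.1 to mm10 and base calling with bcl2fastq 2.17, per the submitters' processing notes and the file headers. The annotation release and the strand setting of the counting are not given in the sources used here. RSEM shares reads that map to several genes between them by probability, and between 8.42% and 9.98% of a library's values were not whole numbers. The tables also hold TPM and FPKM values, per the file headers, which were not used here. The deposited effective lengths, another value in those tables, served as offsets in 1 alternative. Libraries held between 12208522 and 16743144 expected counts, and 3 counts correspond to between 0.179 and 0.246 CPM in a library.

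Each of the 47643 gene IDs was matched to GENCODE mouse release 21 (GRCm38, the assembly also called mm10) for symbol and position. With the version number 39106 IDs matched and without it 47224. The other 419 IDs had no symbol and held at most 0.0612% of a library's counts, and they stayed in the library totals. Where IDs shared a symbol (60 IDs), the ID with more reads kept it. Of 732 members of the gene lists 731 were found, and Krt85 was not. Expected counts were rounded to whole numbers, a shift of at most 0.5 counts.

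The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter, a quasi-likelihood fit and Benjamini-Hochberg adjustment with a threshold of 0.05. Knockout was compared with wild type in the 6 skin libraries and in the 6 epidermis libraries separately, wild type epidermis with wild type skin in those 6 libraries, and the difference of the genotype effects was tested in 1 fit of all 12 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F value. CPM of Adam17 in single libraries use total counts, and all other CPM values, single libraries included, are TMM-scaled. Genes that changed in both tissues were counted among genes tested in both, beside the number that independent lists would share.

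The 35 gene lists, covering skin structures, cell types, cytokines and pathways, were written before the data were examined, as were the tests, the groups and the rule for named genes. A list of sex-linked genes served as a check of the samples and was not tested. The other 34 were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes and a minimum of 3 tested members, and the estimated correlation and fry were alternatives. Named genes were the 10 largest rises and 10 largest falls per tissue among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and an established symbol, up to 4 members of each list with the smallest adjusted p (or its most abundant members if none passed), the 5 genes each way that changed most in both tissues, the 5 smallest adjusted p of the difference between tissues, the 5 largest differences each way between wild type tissues, and Adam17. For a gene with 0 reads in a group the fold is a lower bound against 3 reads over the group, and with 1 to 3 reads it is the ratio of reads per total with an exact 95% interval. Both cover counting error only. Results of some genes that the rule selects are not reported here.

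Alternatives fixed with the design were DESeq2 1.42.0, limma-voom, RLE scaling, TMM without hair, muscle and keratin genes, effective length offsets, no filter on low counts, 1 fit of all 12 libraries, a minimum of 2-fold, a replicate block (for the difference between tissues also by animal), and leaving out each library. Chosen after seeing the data were the share of male RNA (the mean of the Y-linked genes) as a covariate, leaving out the knockout libraries with Y-linked reads, leaving out mitochondrial genes and a robust fit. Groups share replicate numbers, so it was checked whether libraries of the same number deviate together from their group means. In skin the correlations between wild type and knockout libraries of the same number, across genes, were 0.339, 0.359 and 0.206, all above 0.1. Those of different numbers ran from -0.446 to 0.114, so Skin WT 3 with Skin KO 1 (0.114) passed 0.1 too. The numbers were taken to pair the skin libraries, with the pairing coming from the data and not from the labels. So few libraries allow few matchings, so the pairing remains an assumption. In skin the paired fit ended 1 call among the named genes, that of Alas2 (adjusted p = 0.0772). Libraries of 1 group had rank correlations between 0.954 and 0.991 and differed by more than sampling noise (chi-square per degree of freedom of at least 13.3), so they are not copies of each other. That does not show that they came from separate mice. Sex-linked reads, given in the results, do set some libraries within each knockout group apart.

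The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by 1.5-fold to 8-fold, in 10 draws per comparison. An earlier single draw of the wild type tissue comparison gave more than the 10% of false calls set as a limit, after which the number of draws was raised to 10, with that draw among them. The limit was then replaced, after that draw was seen, by one of 6% on the mean with trended dispersions. With gene-wise dispersions the mean share of false calls was 7.28% in skin (3.12% to 12.4% over draws), 7.80% in epidermis (3.47% to 12.8%), 7.85% between wild type tissues (4.42% to 11.0%) and 5.40% for the difference between tissues (0% to 12.4%), above the nominal level of 0.05 in the mean of each. With trended dispersions the means were 5.53%, 4.51%, 4.46% and 5.99%. In skin 88.0% of the false calls with gene-wise dispersions lay in the tenth of genes with the highest dispersion. Genes changed 2-fold were recovered, with gene-wise dispersions, in 21.4% of cases in skin, 63.4% in epidermis, 29.6% between wild type tissues and 13.6% for the difference. For genes changed 4-fold these shares were 85.0%, 89.8%, 85.0% and 63.4%. By camera at an unadjusted p under 0.05, the list of changed genes was found in 10 of 10 draws of each comparison. A list of unchanged genes passed in 1 of 10 for the difference between tissues and in 0 of 10 elsewhere. The simulated genes were drawn independently of each other, while real lists are correlated (estimated at 0.945 for muscle genes in skin). The simulation therefore cannot show how often the preset correlation gives false list calls here.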

Results

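Poly(A) RNA from the skin of 10-week-old C57BL/6 mice was sequenced in 12 libraries. Adam17 encodes a membrane metalloprotease that releases EGFR ligands, TNF and other surface proteins, and the conditional knockout (KO) carried floxed Adam17 alleles together with Sox9-Cre, a Cre recombinase expressed from the Sox9 locus, which is active in the hair follicle lineage. The libraries formed 4 groups of 3, namely whole skin of wild type (WT) mice, whole skin of KO mice, epidermis of WT mice and epidermis of KO mice. Total expected counts per library ranged from 12208522 (Epidermis WT 1) to 16743144 (Skin WT 2). The labels do not say that the 3 libraries of a group came from separate mice. P-values thus measure only the spread between these samples, which may be technical. The sex-linked reads given below argue against repeats of 1 sample for part of the KO libraries. Skin KO 1 held 1728 Y-linked reads and Skin KO 2 held 0, with Xist at 0 and 430. Xist was at 0 in Epidermis KO 1 and at 2511 in Epidermis KO 2. For the WT libraries this stays open. Fold changes are KO against WT unless stated, group levels are means ± SD of TMM-scaled CPM (counts scaled to library size) over n = 3 libraries, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

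Adam17 (ENSMUSG00000052593.15, chromosome 12, 21323509 to 21373632, minus strand) was lower in the knockout in both preparations. In CPM of total counts it stood at 70.3, 110 and 108 in Skin WT and at 46.7, 57.4 and 59.4 in Skin KO, and at 73.2, 82.1 and 67.5 in Epidermis WT and 39.6, 54.3 and 46.3 in Epidermis KO. In skin the level fell from 93.4 ± 13.1 to 55.5 ± 7.16 CPM, a log2 fold change of -0.75 (SE 0.16, adjusted p = 0.00797). In epidermis it fell from 73.8 ± 3.8 to 46.9 ± 5.75 CPM, a log2 fold change of -0.66 (SE 0.12, adjusted p = 0.00213). Every KO library lay below every WT library of its tissue. The counts cover the whole gene, so they do not separate transcripts with and without the floxed part. With the share of Y-linked RNA as a covariate the skin call was lost (log2 fold change -0.59, adjusted p = 0.0805), and it was lost too without the KO libraries that held Y-linked reads (log2 fold change -0.63, adjusted p = 0.17), a fit with 1 KO library whose spread comes from the WT libraries alone. Over 18 alternatives the skin estimate ranged from -0.88 to -0.59 and its adjusted p from 0.000491 to 0.17, and over 17 alternatives the epidermis estimate ranged from -0.76 to -0.52 with an adjusted p of at most 0.046.

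**Figure D1:**
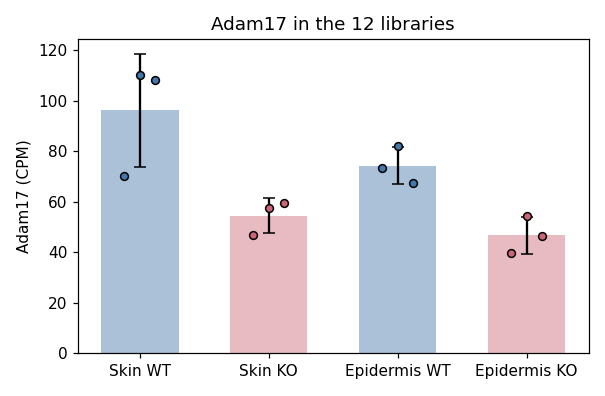
Adam17 in each of the 12 libraries, in CPM of total counts (vertical axis), by tissue and genotype (horizontal axis). Points are libraries, bars are group means and error bars are 1 SD of 3 libraries. The KO libraries lie between 39.6 and 59.4 CPM and the WT libraries between 67.5 and 110 CPM.

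Sex-linked transcripts were not evenly spread over the genotypes. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in all 6 WT libraries and 5435 reads in the KO libraries. Skin KO 1 held 1728, Skin KO 2 0 and Skin KO 3 1034 of them, and Epidermis KO 1, 2 and 3 held 1781, 213 and 679. Xist, the RNA of the inactive X chromosome, had 660, 2193 and 1864 reads in Skin WT, 0, 430 and 319 in Skin KO, 1719, 3222 and 1939 in Epidermis WT, and 0, 2511 and 2050 in Epidermis KO. Skin KO 3, Epidermis KO 2 and Epidermis KO 3 thus held both Xist and Y-linked reads. Skin KO 2 was the only KO library with 0 Y-linked reads. Genotype and the share of male RNA are thus partly confounded in skin. In epidermis every KO library and no WT library held male RNA, so its presence cannot be separated from genotype there.

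**Figure D2:**
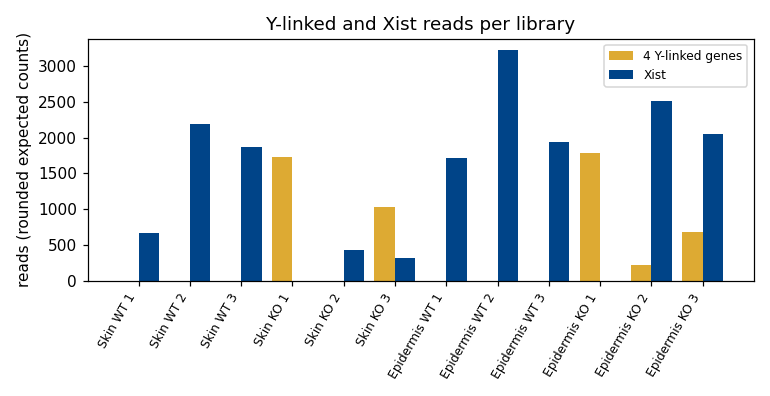
Reads (rounded expected counts, vertical axis) of 4 Y-linked genes together (yellow) and of Xist (blue) in each of the 12 libraries (horizontal axis). The 6 WT libraries have 0 Y-linked reads, and 5 of the KO libraries have between 213 and 1781.

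The first comparison asked which transcripts differ in whole skin when Adam17 is deleted. S100a8 and S100a9, the subunits of the antimicrobial protein calprotectin, rose from near absence. S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721, minus strand) went from 1.27 ± 0.508 to 6154 ± 406 CPM, a log2 fold change of 12.24 (SE 0.43, adjusted p = 1.51e-05), and S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035, plus strand) went from 0.955 ± 0.446 to 3678 ± 44.2 CPM, a log2 fold change of 11.92 (SE 0.45, adjusted p = 1.79e-05). Genes of small proline-rich proteins, which are crosslinked into the cornified envelope of stressed skin, rose with them, and 30 of 31 genes rose in the list that also holds stress keratins and other stress genes. By the same lists 22 of 23 skeletal muscle, 16 of 18 adipocyte, 9 of 12 nerve and 12 of 18 endothelial genes fell (1 endothelial gene rose), and with an estimated correlation these 4 list calls were lost (adjusted p = 0.495, 0.209, 0.351 and 0.397). Of 14906 genes tested, 6780 passed an adjusted p of 0.05, 3310 higher and 3470 lower in the knockout, and 3905 of them changed at least 2-fold (1533 higher, 2372 lower). The groups did not overlap for 58.8% of the genes tested, where chance gives 10%.

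Among the other 8 largest rises, Uox, which encodes urate oxidase, had 1 read over the 3 WT libraries and 9106 over the 3 KO libraries, 10600-fold (95% counting interval 1910 to 420000). Lce3a, a late cornified envelope gene, was at least 987-fold higher (0 against 2537 reads), Ankk1 at least 396-fold higher (0 against 1019 reads), and the pseudogenes Ftl2-ps and Sprr2j-ps at least 880-fold higher (0 against 2261 reads) and at least 518-fold higher (0 against 1332 reads). Sprr2f rose 2910-fold (95% counting interval 806 to 24100) and Sprr2b 2310-fold (95% counting interval 789 to 11200). Sprr2i, with 4 reads in WT, rose from 0.0905 to 178 CPM (SE of the log2 fold change 0.24, adjusted p = 8.51e-06). Members of the Sprr2 family and the pseudogenes are near-identical copies, so reads may have been divided between them and their separate values are uncertain. These bounds and intervals cover counting error only, and a bound is taken against 3 reads over the group.

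Among the largest falls in skin, Upk3b, a uroplakin, was at least 104-fold lower (364 against 0 reads), and the glycosyltransferase gene B4galnt2 at least 38-fold lower (133 against 0 reads). Hamp2, a hepcidin, was 235-fold (95% counting interval 41.8 to 9310) lower, the secretoglobin Scgb1a1 129-fold (95% counting interval 44 to 630) lower, Trim66 145-fold (95% counting interval 25.6 to 5750) lower and Mrgprb9-ps 207-fold (95% counting interval 70.6 to 1010) lower. Nnat, an imprinted gene, fell from 54.8 to 0.405 CPM (adjusted p = 7.42e-05), Rec8, a meiotic cohesin, from 24.2 to 0.177 CPM (adjusted p = 0.000127), Ifitm6 from 81.2 to 0.716 CPM (adjusted p = 0.000445) and Mrgprb11-ps from 41.5 to 0.144 CPM (adjusted p = 0.000326). The last is a pseudogene, as is Mrgprb9-ps, and both can share reads with other Mrgprb genes.

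Of 34 gene lists fixed beforehand, 19 were called in skin by camera with a preset correlation, 13 higher and 6 lower. With an estimated correlation 3 of the calls held. Stress keratins and small proline-rich proteins had the widest rise: 30 of 31 tested members rose, 0 fell and 1 did not pass (30 and 0 adjusted over the list alone), with adjusted p = 6.45e-102, and adjusted p = 0.0171 with an estimated correlation. Its leading members were Sprr2i, Il1f6 (interleukin 36 alpha, log2 fold change of 6.36 (SE 0.18, adjusted p = 1.32e-05)), Sprr2f and Sprr2b. Its median log2 fold change was 8.54, or 7.14 with genes at 0 reads in WT set to their bounds. For antimicrobial proteins 16 of 18 tested members rose, 1 fell and 1 did not pass (16 and 1 adjusted over the list alone), with adjusted p = 5.91e-25, and adjusted p = 0.0171 with an estimated correlation. Slpi, a protease inhibitor of neutrophil elastase, went from 0.529 ± 0.0647 to 106 ± 25.1 CPM, and Lcn2, which binds bacterial siderophores, from 1.4 ± 0.694 to 373 ± 26.3 CPM. For type 17 immunity 13 of 19 tested members rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone), with adjusted p = 1.28e-13, and adjusted p = 0.0171 with an estimated correlation. Il17f was at least 230-fold higher (0 against 590 reads), Il17a rose 400-fold (95% counting interval 71.4 to 15900), Cxcl2 was at least 177-fold higher (0 against 456 reads) and Il23a changed by a log2 fold change of 4.78 (SE 0.34, adjusted p = 0.000178). The regulators Zc3h12a and Nfkbiz rose 16.9-fold (adjusted p = 1.32e-05) and 11.5-fold (adjusted p = 2.15e-05).

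Other immune lists were also called higher. For neutrophils 12 of 14 tested members rose, 2 fell and 0 did not pass (12 and 2 adjusted over the list alone), with adjusted p = 3.05e-22, and adjusted p = 0.0596 with an estimated correlation. The receptor Cxcr2 rose from 0.275 to 32.5 CPM and the stefin Stfa2 by 7.83 on the log2 scale, while S100a8, S100a9 and Il1b (5.31) belong to other lists too. For IL-1 and IL-20 family cytokines 11 of 19 tested members rose, 3 fell and 5 did not pass (11 and 3 adjusted over the list alone), with adjusted p = 1.22e-07, and adjusted p = 0.195 with an estimated correlation, with Il1f8 at 3.49 and Il1f9 at 1.88. Among T cell genes 14 of 21 tested members rose, 2 fell and 5 did not pass (14 and 2 adjusted over the list alone), with adjusted p = 0.000354, and adjusted p = 0.453 with an estimated correlation. Icos rose from 0.27 to 27.6 CPM and the interleukin 2 receptor chain Il2ra from 1.41 to 9.33 CPM, and Trbc2, a T cell receptor constant region, fell 1.66-fold. The type I interferon response moved the other way: 0 of 21 tested members rose, 16 fell and 5 did not pass (0 and 17 adjusted over the list alone), with adjusted p = 6.59e-05, and adjusted p = 0.448 with an estimated correlation. Usp18 fell 5.62-fold and Ifi27l2a 4.88-fold.

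More lists were called higher in skin with a preset correlation. For proliferation genes 23 of 26 tested members rose, 0 fell and 3 did not pass (24 and 0 adjusted over the list alone), with adjusted p = 1.48e-11, and adjusted p = 0.397 with an estimated correlation. Mki67 rose 3.93-fold, Ccnb1 4.33-fold and Top2a 4.23-fold. For barrier lipid synthesis 17 of 23 tested members rose, 1 fell and 5 did not pass (19 and 1 adjusted over the list alone), with adjusted p = 3.09e-05, and adjusted p = 0.458 with an estimated correlation. Sptlc2, of ceramide synthesis, rose 2.58-fold. For the sebaceous gland 12 of 26 tested members rose, 5 fell and 9 did not pass (12 and 5 adjusted over the list alone), with adjusted p = 0.000752, and adjusted p = 0.425 with an estimated correlation. Awat1 rose 9.52-fold and Elovl3 11.8-fold. Among EGFR ligands and receptors, which include substrates of ADAM17, 6 of 11 tested members rose, 2 fell and 3 did not pass (6 and 2 adjusted over the list alone), with adjusted p = 0.00507, and adjusted p = 0.397 with an estimated correlation. Nrg1 rose 37.6-fold, Hbegf 19.6-fold and Epgn 10.8-fold, and Btc fell 15-fold. Among melanocyte genes 7 of 8 tested members rose, 0 fell and 1 did not pass (7 and 0 adjusted over the list alone), with adjusted p = 0.000516, and adjusted p = 0.364 with an estimated correlation. Tyr rose 25.4-fold and Tyrp1 8.23-fold. For immediate early and heat shock genes 8 of 17 tested members rose, 0 fell and 9 did not pass (8 and 0 adjusted over the list alone), with adjusted p = 0.00549, and adjusted p = 0.403 with an estimated correlation. Fosb rose 7.78-fold and Junb 2.55-fold. For the hair shaft and inner root sheath 5 of 37 tested members rose, 0 fell and 32 did not pass (0 and 0 adjusted over the list alone), with adjusted p = 0.00507, and adjusted p = 0.763 with an estimated correlation. Krtap15 stood at 594, 5.72 and 69.7 CPM in the 3 KO libraries, and without Skin KO 1 it lost its call (adjusted p = 0.0779), as did Krt35 (adjusted p = 0.079) and Dsg4 (adjusted p = 0.122). Over all alternatives the adjusted p ran from 0.00211 to 0.689 for Krtap15, from 0.00133 to 0.279 for Krt35 and from 0.00184 to 0.754 for Dsg4.

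With a preset correlation 5 lists of cells found below the epidermis were called lower in whole skin. For skeletal muscle 0 of 23 tested members rose, 22 fell and 1 did not pass (0 and 23 adjusted over the list alone), with adjusted p = 3.08e-06, and adjusted p = 0.495 with an estimated correlation. Pvalb stood at 5469, 750.3 and 1423 CPM in the WT libraries and at 179, 59.95 and 35.7 in the KO libraries. For adipocytes 0 of 18 tested members rose, 16 fell and 2 did not pass (0 and 16 adjusted over the list alone), with adjusted p = 5.39e-11, and adjusted p = 0.209 with an estimated correlation. The beta-3 adrenergic receptor Adrb3 fell 14.1-fold and the lipase Pnpla2 3.08-fold. For fibroblasts and extracellular matrix 0 of 23 tested members rose, 15 fell and 8 did not pass (0 and 16 adjusted over the list alone), with adjusted p = 9.75e-05, and adjusted p = 0.495 with an estimated correlation. Dpt fell 5.14-fold and Dcn 3.2-fold. For endothelium 1 of 18 tested members rose, 12 fell and 5 did not pass (1 and 12 adjusted over the list alone), with adjusted p = 0.000378, and adjusted p = 0.397 with an estimated correlation. Pecam1 fell 2.48-fold, and Flt1, a VEGF receptor, rose 3.42-fold. For Schwann cells and nerve 0 of 12 tested members rose, 9 fell and 3 did not pass (0 and 9 adjusted over the list alone), with adjusted p = 7.09e-05, and adjusted p = 0.351 with an estimated correlation. Pmp22 fell 4-fold.

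The cornified envelope list was not called in skin, and its members went both ways: 12 of 36 tested members rose, 14 fell and 10 did not pass (12 and 14 adjusted over the list alone), with adjusted p = 0.685. Repetin (Rptn) rose from 6.8 to 1784 CPM and caspase 14 (Casp14) 7.86-fold, while Lce1m fell from 1601 to 17.4 CPM and Lce1l 9.19-fold. Hair follicle stem cell genes were split too, with 4 of 23 tested members rose, 10 fell and 9 did not pass (5 and 10 adjusted over the list alone), with adjusted p = 0.136. Plet1 rose 7.27-fold and Krt15 fell 7.11-fold. The remaining lists not called were EGFR and MAPK response (8 rose, 3 fell of 18), ADAM17 partners and substrates (9 rose, 6 fell of 21), Notch pathway (0 rose, 5 fell of 15), type 2 immunity (10 rose, 4 fell of 22), interferon gamma response (2 rose, 7 fell of 21), innate lymphoid cells (5 rose, 2 fell of 13), macrophages and dendritic cells (4 rose, 6 fell of 23), mast cells (3 rose, 4 fell of 13), B cells (3 rose, 1 fell of 5), basal keratinocytes (2 rose, 4 fell of 15), junctions (6 rose, 4 fell of 18), red blood cells (1 rose, 0 fell of 6) and mitochondrial transcripts (0 rose, 5 fell of 13). The mitochondrial list missed the threshold (adjusted p = 0.0532, lower in KO). It passed with the replicate block, which treats same-numbered skin libraries as pairs (adjusted p = 0.0329), and in all in 6 of 10 alternatives (adjusted p from 0.0173 to 0.157). With an estimated correlation it did not pass (adjusted p = 0.688). For junctions the median log2 fold change was 0.21 while the mean and the test were negative. With the KO libraries that held Y-linked reads left out, which leaves 1 KO library, 2658 genes were called in skin. Of the 10 ways to split the 6 skin libraries into 3 and 3, 4, the real one included, called at least 19 lists with the preset correlation, so the number of list calls alone does not set the genotypes apart.

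**Figure D3:**
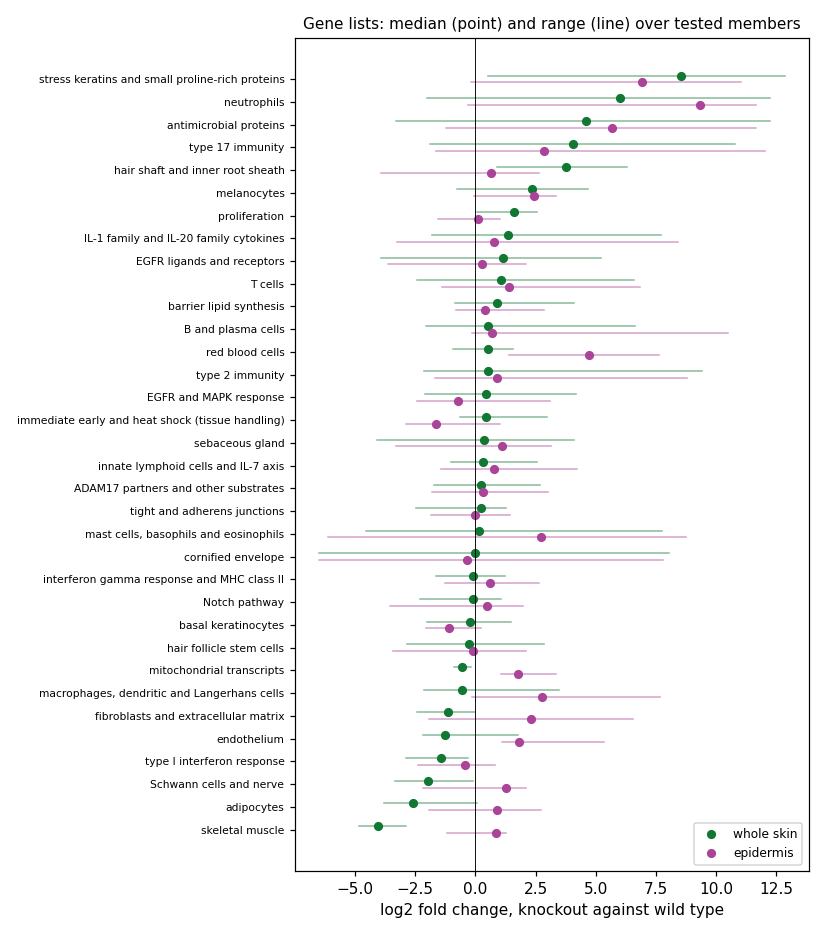
Log2 fold change of knockout against wild type (horizontal axis) for the 34 gene lists (vertical axis) in whole skin (green) and epidermis (purple). Points are medians and lines run from the lowest to the highest member tested. The stress keratin list has medians of 8.54 in skin and 6.93 in epidermis, and the skeletal muscle list has the lowest skin median at -4.07.

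The second comparison asked the same of isolated epidermis. S100a8 and S100a9 were again among the 10 largest rises, here with Il17f. In their lists 15 of 19 macrophage and dendritic cell, 14 of 18 fibroblast (2 fell), 4 of 5 red blood cell and 13 of 13 mitochondrial transcripts rose, and with an estimated correlation these 4 list calls were lost (adjusted p = 0.559 for each). S100a8 rose from 0.736 ± 0.133 to 2421 ± 1350 CPM (log2 fold change of 11.68 (SE 0.59, adjusted p = 5.07e-06)) and S100a9 from 1.55 ± 0.0942 to 3745 ± 2100 CPM (log2 fold change of 11.23 (SE 0.57, adjusted p = 5.07e-06)). Il17f (ENSMUSG00000041872.9, chromosome 1, 20777146 to 20790617, minus strand) was at least 505-fold higher (0 against 1596 reads), and Il17a rose 1620-fold (95% counting interval 290 to 64000). Of 13632 genes tested, 7014 passed, 3570 higher and 3444 lower, and 3261 of them changed at least 2-fold (1671 higher, 1590 lower). The groups did not overlap for 62.2% of the genes tested, where chance gives 10%.

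The other large rises were in Tmprss11b, a membrane serine protease (at least 478-fold higher (0 against 1512 reads)), Fabp7, a fatty acid binding protein (at least 326-fold higher (0 against 1030 reads)), Ankk1 (at least 315-fold higher (0 against 998 reads)) and the ferritin pseudogene Ftl2-ps (at least 334-fold higher (0 against 1058 reads)). Serpinb3a rose from 0.199 ± 0.0987 to 413 ± 115 CPM, a log2 fold change of 10.99 (SE 0.37, adjusted p = 1.47e-06), and Sprr2d from 0.109 ± 0.128 to 273 ± 153 CPM, a log2 fold change of 11.04 (SE 0.70, adjusted p = 1.33e-05). Eif2s3y, on the Y chromosome, was also among the 10 largest rises (at least 368-fold higher (0 against 1164 reads)), and its reads were in the KO libraries that held the other Y-linked reads. The largest falls were in Hamp2 (at least 84-fold lower (239 against 0 reads)), Kel, of the Kell blood group (at least 46-fold lower (131 against 0 reads)), Cys1 (at least 39-fold lower (111 against 0 reads)) and the gastrokine Gkn1 (at least 35.1-fold lower (100 against 0 reads)). With the share of Y-linked RNA as a covariate these 4 lost their calls, with an adjusted p of 1 for each at a fitted log2 fold change of -9.39, -8.49, -8.26 and -8.08, while over the other alternatives they kept them, down to an adjusted p of 3.58e-11, 5.88e-09, 3.22e-08 and 6.77e-08. The covariate is 0 in every WT and above 0 in every KO epidermis library, so it alone can fit their 0 reads in KO. That loss therefore decides nothing about sex. Scgb1a1 was 333-fold (95% counting interval 59.4 to 13200) lower. Mrgprb9-ps fell from 26.5 to 0.224 CPM, Rec8 from 41.2 to 0.447 CPM, Lce1m from 1060 to 11.8 CPM and Mrgprb2, a mast cell receptor, from 7.04 to 0.092 CPM (adjusted p = 6.89e-05). Gng13 fell from 11.9 to 0.144 CPM and lost its call with that covariate (log2 fold change -4.00, adjusted p = 0.071, the highest over its alternatives, the lowest being 1.39e-19).

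In epidermis 16 of the 34 lists were called, 14 higher and 2 lower. With an estimated correlation 0 calls held, although 2 lists had an unadjusted p under 0.05 there and fry, which asks whether a list's genes move on balance one way, called 24. For stress keratins 28 of 30 tested members rose, 0 fell and 2 did not pass (28 and 0 adjusted over the list alone), with adjusted p = 9.48e-36, and adjusted p = 0.559 with an estimated correlation. Il1f6 rose 43-fold and the near-identical Sprr2a2 and Sprr2a3 by 7.13 and 7.18 on the log2 scale. For antimicrobial proteins 11 of 14 tested members rose, 2 fell and 1 did not pass (11 and 2 adjusted over the list alone), with adjusted p = 7.75e-08, and adjusted p = 0.559 with an estimated correlation. Lcn2 rose from 0.171 to 163 CPM and Pglyrp3 6.09-fold. For neutrophils 10 of 11 tested members rose, 0 fell and 1 did not pass (10 and 0 adjusted over the list alone), with adjusted p = 3.78e-11, and adjusted p = 0.559 with an estimated correlation. Cxcr2 rose 1020-fold (95% counting interval 283 to 8450). For type 17 immunity 14 of 18 tested members rose, 2 fell and 2 did not pass (14 and 3 adjusted over the list alone), with adjusted p = 8.59e-07, and adjusted p = 0.559 with an estimated correlation. Ccl20, the ligand of Ccr6, rose 15.9-fold. For IL-1 and IL-20 family cytokines 11 of 18 tested members rose, 3 fell and 4 did not pass (11 and 3 adjusted over the list alone), with adjusted p = 0.0111, and adjusted p = 0.559 with an estimated correlation. Il1f8 rose 10.4-fold and the decoy receptor Il1r2 fell 3.47-fold.

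With a preset correlation 3 other immune lists were called higher in epidermis. For macrophages, dendritic and Langerhans cells 15 of 19 tested members rose, 0 fell and 4 did not pass (17 and 0 adjusted over the list alone), with adjusted p = 3.09e-06, and adjusted p = 0.559 with an estimated correlation. Lyz2 rose from 0.688 to 31.9 CPM, the complement gene C1qb from 0.125 to 6.68 CPM and Ccr2 237-fold (95% counting interval 65.2 to 1960). For T cells 14 of 21 tested members rose, 1 fell and 6 did not pass (14 and 1 adjusted over the list alone), with adjusted p = 0.000334, and adjusted p = 0.58 with an estimated correlation. Icos rose from 0.275 to 32 CPM and Ctla4 12.7-fold. For type 2 immunity 11 of 18 tested members rose, 3 fell and 4 did not pass (12 and 4 adjusted over the list alone), with adjusted p = 0.0484, and adjusted p = 0.559 with an estimated correlation. Ccl11 was at least 30.3-fold higher (0 against 96 reads), Ccl8 rose 50.2-fold and Ccl22 4.71-fold. The type 2 call was lost without Epidermis KO 2 (adjusted p = 0.102) and with RLE factors (adjusted p = 0.0505), and over its alternatives other than the estimated correlation the adjusted p ran from 0.00162 to 0.102.

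With a preset correlation the lists of fibroblasts, endothelium, red blood cells and mitochondrial transcripts were called higher, and those of adipocytes, skeletal muscle and Schwann cells were not called. For fibroblasts and matrix 14 of 18 tested members rose, 2 fell and 2 did not pass (14 and 2 adjusted over the list alone), with adjusted p = 0.00266, and adjusted p = 0.559 with an estimated correlation. Col3a1 rose from 1.08 to 25.4 CPM and Dpt 30.6-fold, while Sparc fell 2.9-fold. For endothelium 3 of 6 tested members rose, 0 fell and 3 did not pass (6 and 0 adjusted over the list alone), with adjusted p = 0.0328, and adjusted p = 0.58 with an estimated correlation. Flt1 rose 40.8-fold. For red blood cells 4 of 5 tested members rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone), with adjusted p = 0.00662, and adjusted p = 0.559 with an estimated correlation. The globin Hbb-bs stood at 4.98, 6.99 and 1.56 CPM in Epidermis WT and at 407, 639.7 and 91.5 in Epidermis KO, and its near-identical copy Hbb-bt rose 198-fold. For mitochondrial transcripts 13 of 13 tested members rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone), with adjusted p = 8.67e-05, and adjusted p = 0.559 with an estimated correlation. They made up 8.71 ± 2.2% of counts in Epidermis KO and 2.86 ± 0.743% in Epidermis WT (mean ± SD, n = 3). Nuclear copies of these genes can share their reads. For the sebaceous gland 15 of 24 tested members rose, 5 fell and 4 did not pass (16 and 5 adjusted over the list alone), with adjusted p = 0.000378, and adjusted p = 0.559 with an estimated correlation. Elovl5 rose 5.07-fold and Far1 2.94-fold. For barrier lipid synthesis 12 of 23 tested members rose, 3 fell and 8 did not pass (12 and 3 adjusted over the list alone), with adjusted p = 0.0389, and adjusted p = 0.6 with an estimated correlation. Degs2 rose 7.29-fold. That call was lost with the replicate block (adjusted p = 0.0518), without Epidermis WT 1 (adjusted p = 0.155) and without Epidermis KO 1 (adjusted p = 0.0676), and over the alternatives other than the estimated correlation the adjusted p ran from 0.00916 to 0.155.

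With a preset correlation the lists of immediate early and basal keratinocyte genes were called lower in epidermis. For immediate early and heat shock genes 3 of 17 tested members rose, 12 fell and 2 did not pass (3 and 12 adjusted over the list alone), with adjusted p = 3.8e-05, and adjusted p = 0.559 with an estimated correlation. Atf3 stood at 1598, 2415 and 1872 CPM in WT and at 194, 340.4 and 256 in KO, and Ier2 fell 6.11-fold and Junb 3.67-fold. For basal keratinocytes 0 of 15 tested members rose, 10 fell and 5 did not pass (0 and 10 adjusted over the list alone), with adjusted p = 0.000251, and adjusted p = 0.559 with an estimated correlation. Lamb3, a laminin chain of the basement membrane, fell 4.16-fold, Col17a1 3.62-fold and Dst 4.16-fold. Lists not called were cornified envelope (10 rose, 17 fell of 36), proliferation (6 rose, 5 fell of 26), EGFR ligands (5 rose, 1 fell of 11), EGFR and MAPK response (5 rose, 10 fell of 18), ADAM17 partners and substrates (8 rose, 3 fell of 19), Notch pathway (6 rose, 5 fell of 12), type I interferon (0 rose, 6 fell of 13), interferon gamma (9 rose, 1 fell of 19), innate lymphoid cells (6 rose, 1 fell of 12), mast cells (4 rose, 1 fell of 5), B cells (3 rose, 0 fell of 5), hair shaft (4 rose, 2 fell of 27), hair follicle stem cells (4 rose, 8 fell of 23), melanocytes (6 rose, 0 fell of 8), junctions (5 rose, 4 fell of 18), adipocytes (5 rose, 1 fell of 10), skeletal muscle (1 rose, 2 fell of 9) and Schwann cells (4 rose, 1 fell of 7). For Notch (median log2 fold change 0.47) and proliferation (0.10) the test pointed down while the median was above 0. With the share of Y-linked RNA as a covariate 4540 genes were called in epidermis, and 4 of the 10 splits of its 6 libraries called at least 16 lists.

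Several lists without a call held genes that moved apart. Among EGFR and MAPK response genes the receptor tyrosine kinase inhibitors Spry1 and Spry2 fell in epidermis, 5.37-fold and 3.73-fold (adjusted p = 5.72e-05 and 0.000167, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), while Phlda1 rose 8.69-fold, the ephrin receptor Epha4 4.11-fold and Epha2 2.61-fold. In skin Spry1 fell 4.26-fold, and Phlda1 and Epha2 rose 7.1-fold and 3.9-fold. Among Notch pathway genes the ligand Dll1 fell in both tissues, 2.65-fold in skin and 3.45-fold in epidermis, and the Notch target Hes1 fell 11.8-fold in epidermis with a log2 fold change of -0.02 in skin (adjusted p = 0.000528 for the difference). Rbpj, the DNA-binding partner of Notch, rose 1.9-fold in epidermis. Among other ADAM17 substrates and partners Cd44 rose 4.22-fold in skin and 5.16-fold in epidermis, Il6ra fell 3.32-fold and 1.88-fold, and Adam10, a related protease, rose 2.33-fold in epidermis.

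In epidermis Ciita, the regulator of MHC class II genes, rose 6.2-fold and H2-Aa 3.08-fold, and in skin they had log2 fold changes of 0.62 and 0.24 that did not pass (adjusted p = 0.0121 and 0.0172 for the difference). Ear1, an eosinophil-associated ribonuclease with near-identical family members, rose 298-fold (95% counting interval 52.9 to 11800) in skin and 577-fold (95% counting interval 103 to 22800) in epidermis. The B lymphoid kinase gene Blk, which gamma delta T cells also express, rose from 0.144 to 13.9 CPM in skin and was at least 174-fold higher (0 against 551 reads) in epidermis. Il7r, the interleukin 7 receptor, rose 5.51-fold and 18.6-fold, and the lymphotoxin Ltb 4.89-fold and 6.4-fold. The follicle stem cell gene Cd34 fell 4.95-fold and 6.41-fold, and the transcription factor Runx1 rose 4.43-fold and 4.24-fold. The tight junction gene Cgn fell 5.6-fold and 3.48-fold, and Cldn23 3.46-fold and 3.6-fold.

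S100a8, S100a9, Ankk1, Ftl2-ps and Il17f led the genes that rose in both tissues, and Hamp2, Scgb1a1, Mrgprb9-ps, Rec8 and Lce1m led those that fell in both. Lce1m fell by similar amounts, -6.52 in skin and -6.49 in epidermis, and Rptn rose by 8.04 and 7.79. Of 13339 genes tested in both, 3531 changed the same way, 1904 higher and 1627 lower. Independent lists would share 843.7 and 652.3 genes. Whole skin includes epidermis, and in both tissues Y-linked reads were found only in KO libraries. The lists were thus not independent to begin with, and the excess is no separate support for either. Another 237 changed in opposite directions, 147 of them lower in skin and higher in epidermis. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.715 and Spearman's rho of 0.592. With the share of Y-linked RNA as a covariate 1843 genes changed the same way in both tissues.

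**Figure D4:**
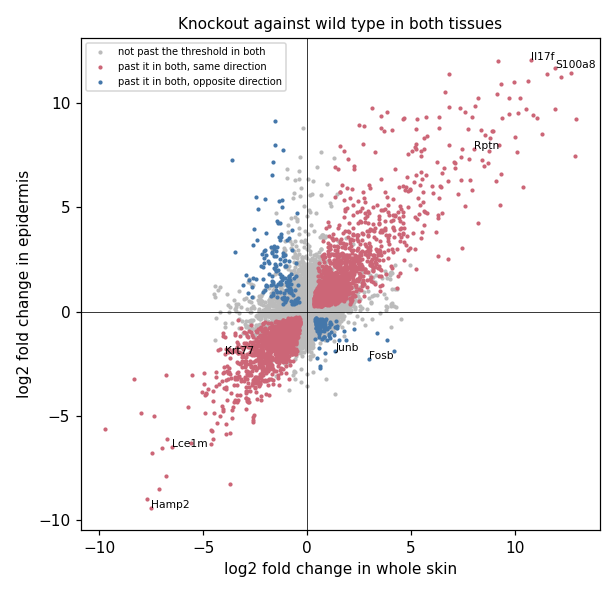
Log2 fold change of knockout against wild type in whole skin (horizontal axis) and in epidermis (vertical axis) for the 13339 genes tested in both. Each point is a gene; red points changed the same way in both tissues (3531), blue points changed in opposite directions (237) and grey points did not pass in both.

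The next comparison asked where the genotype effect itself differs between skin and epidermis. Junb, an AP-1 transcription factor, rose in skin and fell in epidermis, with a log2 difference (skin minus epidermis) of 3.15 (SE 0.21, adjusted p = 0.000116), and Myc did the same with 2.23 (adjusted p = 0.000207). The fatty acid transporter Cd36 fell in skin and rose in epidermis, differing by -5.32 (adjusted p = 0.00014), as did Eepd1, by -4.25 (adjusted p = 0.00021). Ass1, which makes the precursor of arginine, rose 5.83-fold in skin and was at a log2 fold change of 0.26 in epidermis, a difference of 2.21 (adjusted p = 0.000207). In all, 2539 of 15394 genes differed, 979 with the higher effect in skin and 1560 with the higher effect in epidermis. Higher refers to the signed log2 fold change, so a higher effect can also be a smaller fall. Of the 34 lists 21 were called, 11 and 10 in these directions. With an estimated correlation 2 held, immediate early genes (adjusted p = 0.0239) and adipocyte genes (adjusted p = 0.0239).

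By list, 21 of 26 proliferation genes had the higher effect in skin (adjusted p = 9.71e-21, and 0.0993 with an estimated correlation). So had 7 of 15 basal keratinocyte genes (adjusted p = 1.2e-05, and 0.261 with an estimated correlation), and 11 of 17 immediate early genes, Fosb by 5.14 and Fos by 3.16. Basal keratinocyte genes had a median log2 fold change of -0.21 in skin and -1.08 in epidermis, so they fell more in epidermis. The effect was higher in epidermis for 18 of 23 fibroblast genes (adjusted p = 9.2e-20; adjusted p = 0.0993 with an estimated correlation), 14 of 18 endothelial genes (adjusted p = 1.48e-13; adjusted p = 0.0993 with an estimated correlation), 12 of 24 macrophage and dendritic cell genes (adjusted p = 2.81e-13; adjusted p = 0.127 with an estimated correlation) and all 13 mitochondrial transcripts (adjusted p = 2.76e-15; adjusted p = 0.11 with an estimated correlation). Also higher in epidermis were 5 of 6 red blood cell genes (adjusted p = 3.57e-05, and 0.185 with an estimated correlation), 12 of 23 muscle genes (adjusted p = 1.58e-12, and 0.28 with an estimated correlation) and 13 of 18 adipocyte genes. For muscle the median log2 fold change was -4.07 in skin, against 0.86 for the 9 genes tested in epidermis, so the larger change was the fall in skin. For adipocytes the medians were -2.58 in skin and 0.92 in epidermis. The count of genes depended on single libraries: it was 3940 without Skin WT 1, 1436 without Skin WT 3, 1393 without Skin KO 2, 1581 without Epidermis WT 3 and 1412 without Epidermis KO 2.

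Wild type epidermis was compared with wild type skin to see what the preparations hold. Muscle genes were far lower in epidermis, led by Myl1 (log2 difference -14.31), Rpl3l (-13.80), Mylk4 (-13.54), Smyd1 (-13.48) and Xirp2 (-13.40), and these fitted values rest on at most 3 reads in epidermis and set no fold. Immediate early genes were higher in epidermis, led by Egr4 (8.90), Fosb (8.21), Atf3 (6.26), the synaptic gene Arc (5.85) and Fos (5.78). The value of Egr4 is fitted against 0 reads in Skin WT and sets no fold either. Of 14596 genes tested, 6258 differed, 2561 higher and 3697 lower in epidermis, and 3653 differed at least 2-fold. All 23 fibroblast, 23 muscle, 18 endothelial and 12 Schwann cell genes tested were lower in epidermis, as were 17 of 18 adipocyte and 19 of 20 macrophage and dendritic cell genes. In this comparison 14 lists were called, and 5 held with an estimated correlation, those of fibroblasts, adipocytes, endothelium, macrophages and dendritic cells, and Schwann cells (adjusted p = 0.0376 for each). Muscle genes had an adjusted p of 5.44e-19, and adjusted p = 0.335 with an estimated correlation, and immediate early genes 8.89e-25, and adjusted p = 0.0784 with an estimated correlation.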

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

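The tests with the male RNA share, of immediate early genes across the tissues and of carried-over skin RNA were chosen only after the results were seen, and the test of the difference between tissues was planned. The genotype effect differed between skin and epidermis for 2539 genes and, with a preset correlation, for 21 gene lists, of which 2 held with an estimated correlation (immediate early genes and adipocytes). The named genes among them are given with the log2 difference, skin minus epidermis. The difference is signed, so a higher effect in a tissue can also be a smaller fall there. In the knockout libraries 5435 reads came from 4 Y-linked genes, against 0 in wild type.

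Named genes with the higher effect in skin were the immediate early and heat shock genes Junb (3.15), Fosb (5.14), Fos (3.16), Ier2 (3.16), Atf3 (3.10), Egr2 (1.97) and Dnajb1 (1.65), and also Myc (2.23), Ass1 (2.21), Socs3 (2.33), Zc3h12a (1.90), Nfkbiz (2.46) and Slpi (2.45). EGFR genes went both ways, with Hbegf (4.02), Nrg1 (3.13), Areg (2.43), Epgn (1.26) and Ier3 (1.08) above 0 and Epha4 (-1.01) below. Among EGFR ligands and receptors 5 of 11 were higher and 1 lower, among EGFR and MAPK response genes 5 of 18 were higher and 2 lower, and both list calls were lost with an estimated correlation (adjusted p = 0.39 and 0.28). Named proliferation genes had Ccnb1 (1.56), E2f1 (1.56), Aurkb (1.53), Mcm6 (1.52), Plk1 (1.47) and Top2a (1.11). Other named genes above 0 were Krtap3-2 (5.20), Krt32 (4.06), Hes1 (3.46), Dgat2l6 (2.95), Krt14 (1.65), Plet1 (1.27), Lamb3 (1.26), Cldn4 (1.19), Lfng (1.08), Ifitm3 (1.06), Far1 (0.88), Cxcl16 (0.77) and Icam1 (0.70). Of Notch genes 3 were higher and 3 lower of 15, of sebaceous gland genes 3 and 2 of 26. For hair follicle stem cells it was 1 and 1 of 23, for ADAM17 partners 2 and 3 of 21. These 4 lists were not called. For the hair shaft 2 of 37 were higher, and its call was lost by camera with an estimated correlation (adjusted p = 0.628).

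Named genes with the higher effect in epidermis were, of fibroblasts and fat, Dpt (-7.38), Col3a1 (-5.34), Retn (-5.13), Dcn (-4.60), Plin4 (-4.46), Lpl (-3.87), Mmp2 (-2.37), Adrb3 (-1.97), Pnpla2 (-1.59) and Adipor2 (-0.55). Of vessels they were Emcn (-7.62), Eng (-3.91), Pecam1 (-3.68), Flt1 (-3.66) and Esam (-2.61), of muscle Pvalb (-6.60), Tpm2 (-4.43) and Ryr1 (-3.09), and of nerve Cnp (-2.52), Ncmap (-2.39) and Prx (-2.21). Globins and Alas2, a heme enzyme, had Hbb-bt (-7.05), Hbb-bs (-6.40), Hba-a2 (-4.36) and Alas2 (-3.19). Leukocyte and chemokine genes had Ccl11 (-9.76), C1qb (-6.41), Ccr2 (-5.99), Lyz2 (-5.98), Hdc (-5.24), Ccl8 (-4.29), Il2ra (-3.08), Cxcr2 (-3.06), Tnfrsf1b (-2.01), Ighm (-1.99), Il7r (-1.84), Ccr4 (-1.53), Il6ra (-0.90) and Thy1 (-0.71). Apart from macrophages, the lists that hold them were not called for the difference. The effect was higher in epidermis for 2 of 23 T cell, 2 of 17 neutrophil, 1 of 13 mast cell and 1 of 6 B cell genes, and higher in skin for 0. For type 2 immunity it was higher in epidermis for 6 of 23 genes and in skin for 1, and for innate lymphoid cells for 5 of 14 and 1. Interferon and MHC class II genes had Gbp3 (-3.91), Ciita (-2.10), Gbp6 (-1.72), Gbp7 (-1.66), Ifi27l2a (-1.51), H2-Aa (-1.47) and H2-Eb1 (-1.20), and mitochondrial transcripts mt-Atp8 (-3.59), mt-Nd5 (-2.74), mt-Nd2 (-2.66), mt-Nd4 (-2.63), mt-Atp6 (-2.44), mt-Co3 (-2.40) and mt-Co2 (-2.04). In their lists the effect was higher in epidermis for 18 of 23 fibroblast, 14 of 18 endothelial, 12 of 23 muscle, 6 of 12 Schwann cell, 5 of 6 red blood cell, 12 of 24 macrophage, 4 of 22 type I interferon, 8 of 22 interferon gamma and 13 of 13 mitochondrial genes. These list calls were lost with an estimated correlation (adjusted p = 0.0993, 0.0993, 0.28, 0.0895, 0.185, 0.127, 0.508, 0.32 and 0.11), while that of adipocytes, 13 of 18, held. Others were Nnat (-8.12), Cd36 (-5.32), Trim66 (-5.02), Igfbp5 (-4.33), Eepd1 (-4.25), Acacb (-2.20) and Rbpj (-0.72). The values of Ccl11, Ccr2, Cxcr2, Emcn, Retn and Trim66 are fitted against at most 3 reads in 1 group and set no bound.

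Y-linked reads were found in 5 of the 6 knockout libraries, so part of the genotype differences might follow the sex of the mice. With the male RNA share as a covariate 66.5% of the genes called in skin and 62.3% of those in epidermis were still called. Of the genes called without it 100%, after rounding, kept their direction in each tissue. The median ratio of the log2 fold changes was 1.10 in skin and 1.01 in epidermis. These values do not decide whether sex is the cause. Eif2s3y, a Y-linked gene, also kept its call in epidermis with this covariate, so a kept call can still follow sex. No epidermis KO library was free of Y-linked reads, and in skin only Skin KO 2 was. For the genes that lost their call sex stays open too, since the standard errors also grew, to 1.39 and 1.43 times their size in the median. Why Skin KO 3, Epidermis KO 2 and Epidermis KO 3 hold both Xist and Y-linked reads was not tested.

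Of 17 immediate early and heat shock genes 12 fell and 3 rose in knockout epidermis, with a median log2 fold change of -1.65 and a list call that was lost with an estimated correlation (adjusted p = 0.559), and in knockout skin members rose or did not pass. The list's difference between tissues had an adjusted p of 0.0239 by camera with an estimated correlation. Wild type epidermis exceeded wild type skin by a median of 3.82 on the log2 scale, so a response to preparing the epidermis that is stronger in wild type samples has the values it needs and is a candidate explanation. A lower level in living knockout epidermis stays open too, as no library of unprocessed epidermis was used here.

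In knockout epidermis 4 of 5 red blood cell, 14 of 18 fibroblast, 3 of 6 endothelial and 15 of 19 macrophage genes rose, with list calls that were lost with an estimated correlation (adjusted p = 0.559, 0.559, 0.58 and 0.559) and with Hbb-bs up to 639.7 CPM, Lyz2 at 31.9 and Col3a1 at 25.4 CPM in the mean, which could come from whole skin carried over into the preparation. The rise of the median red blood cell gene would need 704% of the RNA of knockout skin, which argues against carry-over of whole skin for these genes. Carry-over from a source other than whole skin was not tested. For fibroblast genes the median need was 9.09%, for endothelial genes 13.7% and for macrophage genes 20.6%, while the median adipocyte gene needed 0.999% and the median muscle gene 0.334%. The muscle genes end at 0.497% at their upper quartile, below the lower quartile of the fibroblast genes (4.23%), which argues against carry-over of whole skin with its muscle. The adipocyte genes reach 7.81% at theirs, so for fibroblast genes carry-over of skin without its muscle layer and a change within the epidermis cannot be told apart.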

How the results depend on the processing

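The robust fit, the male RNA share as a covariate, and the fits without mitochondrial genes or without the knockout libraries that held Y-linked reads were chosen only after the results were seen, and the other alternatives were fixed before. Of 5067 values of named genes under the alternatives (290 gene and tissue pairs), 4955 kept their direction and their side of the threshold, 112 kept the direction and lost the call, and 0 turned. The male RNA share ended 23 of the calls and leaving out the libraries with Y-linked reads, which leaves 1 knockout library in skin, ended 28. In epidermis Hamp2, Kel, Cys1 and Gkn1, at 0 reads in the knockout, lost their calls with the male RNA share at the same fitted log2 fold change. The covariate alone can fit those 0 reads, so these losses decide nothing about sex. Leaving out single libraries ended 38. Alas2 in skin was the least stable and lost its call in 16 of 18, with an adjusted p from 0.0371 to 0.669. No scaling moved the median of all genes by more than 0.034 on the log2 scale. The named genes were mostly chosen from these same data for large or clear changes, so their stability was largely built in. Over all genes called, the male RNA share kept 66.5% of the calls in skin and 62.3% in epidermis.

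Requiring at least 2-fold left 3905 genes in skin, 3261 in epidermis, 3653 between wild type tissues and 1637 changed the same way in both tissues, as the rule itself removes genes. With the male RNA share 4540 genes were called in epidermis, 4372 of them also called without it, and 1843 in both tissues, and the standard errors with it were 1.39 times (skin) and 1.43 times (epidermis) as large in the median. Without the knockout libraries that held Y-linked reads 2658 genes were called in skin with fewer libraries, 2539 of them also called with all libraries. A block by animal, which assumes that same-numbered libraries of both tissues came from 1 mouse, gave 1271 genes whose effect differs between tissues, and the cause was not tested. Skin KO 2 held 0 Y-linked reads and Epidermis KO 2 held 213, which argues against that assumption for this pair. With an estimated correlation camera called 3 lists in skin and 0 in epidermis, where 2 had an unadjusted p under 0.05 and fry called 24. The estimated correlation, 0.945 for muscle genes in skin, replaces the preset one of 0.01. With fry the hair shaft (adjusted p = 0.226) and muscle (0.0523) calls in skin were lost, from lowest values of 5.4e-21 and 5.17e-15 over the alternatives. Of lists not called, mitochondrial transcripts in skin and B and plasma cells in epidermis gained a call in 6 of 10 alternatives, type 2 immunity in skin in 5, melanocytes in epidermis in 4, and 12 other lists in 1 to 3.

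Leaving out 1 library gave 4944 to 7770 genes in skin, 5856 to 6573 in epidermis, 4198 to 7830 between wild type tissues, 1393 to 3940 for the difference between tissues, 2654 to 3672 in both tissues, 19 to 22 lists in skin and 16 to 19 in epidermis. The highest counts in skin, between wild type tissues and for the difference all came without Skin WT 1.

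With the replicate block 6567 genes were called in skin, 6765 in epidermis, 5231 between wild type tissues, 2152 for the difference and 3385 in both tissues, with 20 lists in skin and 19 in epidermis. In skin, where the numbers were taken to pair the libraries, it changed no other call of a named gene than that of Alas2. In epidermis same-numbered libraries correlated at 0.075, 0.14 and -0.055, and across tissues between -0.244 and 0.03, so there the libraries share only a number, and not every library correlated best with its own number.

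The real split of the 6 libraries called 6780 genes in skin, 7014 in epidermis and 6258 between wild type tissues, and the highest of the other 9 splits called 0 in each by edgeR, but 10 splits are too few for a share under 0.05. In skin, 3 other splits also part all 3 assumed pairs, and they called 0 genes. Every split but the real one mixes genotypes (or tissues) within its groups. That adds their effect to the spread within groups, so these 0 calls decide nothing. For lists the splits are likewise too few. The real split called 19 lists in skin and the highest other 22, and in epidermis 16 and 21, and 4 of the 10 splits reached the real number in each. For the difference between tissues (2539 genes, highest of 99 other drawn regroupings 1711, 1 of 100 as large) the comparison decides nothing. Regroupings that mix genotypes add the genotype effect to the spread within groups. In the 80 regroupings whose skin split parts the 3 pairs, run after the result was seen, 78 mix genotypes, with a common dispersion (square root) of 0.375 to 0.532 against 0.231 and at most 1783 genes, and exchanging the epidermis genotypes called 8544. For genes changed the same way in both tissues (3531, highest other 237, 1 of 100 pairs of splits as large) the comparison decides nothing either, as every other split of a tissue called 0 genes and so shares 0, and 237 is the real grouping with 1 tissue's genotypes exchanged. With gene-wise dispersions a change of 1.5-fold was recovered in 1.2% of simulated cases in skin and 16.8% in epidermis. With trended dispersions it was recovered in 3.8% and 27.2%. The simulation changed 200 genes, far fewer than were called in the data, which makes its adjusted threshold stricter. These rates therefore do not show how often small changes were missed here.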
